A study of Homo sapiens with 16 samples.

How the data were processed

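The study measured RNA labelled with 5-ethynyl uridine (EU) in the human endometrial cancer cell line HEC-1-A, in 16 libraries: control and METTL3 knockdown, 4 EU times (10, 20, 30 and 60 min) and 2 libraries per group. Per the labels, cells were seeded on 8 plates and EU was added to 0.5 mM after 48 h. RNA carrying EU was captured by click chemistry, 0.01 µl of ERCC spike-in was added to each sample after capture, and libraries were made with a stranded total RNA kit. The labels also call the molecule polyA RNA. They do not say how METTL3 was knocked down, nor whether the 2 libraries of a group come from separate plates.

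The deposited files hold raw counts per gene and per ERCC species, with no normalization. Per the submitters' processing notes, reads were processed with CASAVA, Trimmomatic 0.38, HISAT2 2.1.0 and HTSeq on hg38. The strand and feature settings of HTSeq are not given there, so counts of antisense, overlapping and multi-copy genes are uncertain. All 58721 human gene identifiers matched the GENCODE 29 basic annotation, from which symbols, classes and positions were taken, and the counts in the series table and the files per sample differed in 0 values. The libraries listed 23039387 to 25642773 reads, and of those 22.2% to 40.6% were counted on human genes, 0.575% to 13.8% on ERCC species, 46.2% to 63.2% on no feature, 0.698% to 1.39% were ambiguous and 8.88% to 11.5% were not uniquely aligned. Between 18201 and 33271 genes and 65 to 86 of 92 ERCC species were detected per library. Reads are not independent molecules, so floors cover counting error only.

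The design, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Genes were kept with edgeR's filterByExpr (19072 genes), scaled by TMM over human genes, and fitted with quasi-likelihood models of the 8 groups, which share 1 estimate of the spread (common dispersion 0.0282, median prior degrees of freedom 10.5). Contrasts were the mean over EU times of knockdown minus control, the same at each time, the interaction with EU time (an F test), and trends linear in log2 EU minutes within each condition. The mean contrast was also fitted with library scaling from total ERCC counts. The Benjamini-Hochberg threshold was 0.05.

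Captured RNA was the ratio of human gene counts to ERCC counts. Its log2 difference and the difference of its least-squares slopes on EU minutes were tested by exact two-sided permutation of condition labels within EU time (1296 assignments). Slopes per gene used ERCC-scaled counts of genes with a mean of at least 50 counts, with 100 permutation draws. Shares of 8 annotation classes and of reads outside annotated exons were tested by the same exact permutation, with adjustment over the 9.

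Gene lists were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01) and again with an estimated correlation and with fry, a test that does not compare a list with other genes. The 25 lists were the m6A writer complex, m6A readers and erasers, nuclear RNA surveillance, chromatin regulators, Polycomb and heterochromatin, immediate-early genes, interferon-stimulated genes, p53 targets, the integrated stress and unfolded protein response, heat shock, AKT and mTORC2 regulators, cholesterol biosynthesis, hypoxia and glycolysis, NF-kB targets, TGF-beta response and epithelial-mesenchymal transition, epithelial and endometrial identity, S phase, G2/M, replication-dependent histones, ribosomal proteins, mitochondrially encoded genes, RNA polymerase III and snRNA transcripts, snoRNA host genes, nuclear-retained long non-coding RNAs and markers of other cell types. A gene can stand in more than 1 list, as BTG2 and IER3 do. Where a whole group had no counts, list medians were also computed with such genes at a floor of 3 counts over the group. This touched 10 lists and moved a median by up to 1.02.

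The named genes were METTL3, the 12 largest rises and 12 largest falls past the threshold with at least 5 CPM on average and 1 direction at all EU times, the 10 largest of each in the control trend, the 6 lowest p of the interaction, and up to 4 members per list with the lowest p. The control trend genes had the same filters, except that the same direction in knockdown-labelled libraries replaced 1 direction at all EU times. Further genes in the closing part on EU time in knockdown-labelled libraries were chosen after their values were seen, as were the extra members given by EU time.

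The models were tested on simulated data of the same design. For the mean contrast, 37 of 65 genes changed 1.5-fold, 51 of 67 changed 2-fold and 62 of 65 changed 4-fold were recovered, with 6 false calls (3.85%). The run on the ERCC scale gave 5 false calls (3.23%). Its simulated spike-in totals were set to the true library scale without spike-in error, so it does not test ERCC scaling. The interaction gave 1 false call. A simulated log2 slope ratio of 0.585 was recovered as 0.581 but not called (permutation p = 0.3), and a ratio of 0 as -0.00213 (permutation p = 0.88).

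The alternatives were other scaling (RLE, upper quartile, median-of-ratios ERCC factors), no filter, a mean of at least 5 CPM, DESeq2, an additive model, a replicate block, EU times left out, each library left out, groups summed, labels exchanged by whole group, other set tests and other slopes. A fit with 1 library left out takes the spread of the lone library from the other groups. No library was left out of the main comparisons. Tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.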

Results

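The data were counts of newly made RNA from HEC-1-A, an established human endometrial cancer cell line, in 16 sequencing libraries. Cells were given 5-ethynyl uridine (EU), a uridine analogue that enters RNA as it is made, for 10, 20, 30 or 60 min, and EU-labelled RNA was captured before sequencing. At each EU time there were 2 libraries labelled control and 2 labelled METTL3 knockdown, so each condition had 8. METTL3 is the catalytic subunit of the enzyme that writes N6-methyladenosine (m6A) on RNA. The libraries listed 23039387 to 25642773 reads, of which 5187965 to 10023148 were counted on human genes, with a median of 6780339. Counts on the ERCC spike-in RNAs, a fixed volume of synthetic transcripts added after capture, ran from 138753 to 3293823. The labels give 8 plates for 8 groups, so the 2 libraries of a group may come from 1 plate, and every p below measures only the spread between libraries.

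METTL3 (ENSG00000165819.11, hg38 chromosome 14, 21498133 to 21511375, minus strand) was read in every library before any other gene. In control libraries it had 97.9 and 96.8 CPM (counts scaled to library size) at 10 min, 96.3 and 98.1 at 20 min, 103 and 101 at 30 min, and 87.1 and 88.1 at 60 min. In libraries labelled knockdown METTL3 had 111 and 87.7 CPM at 10 min, 98.7 and 78.3 at 20 min, 82.6 and 67.4 at 30 min, and 86.9 and 87.5 at 60 min. The means were 96.1 ± 5.77 and 87.6 ± 13.1 CPM (SD, n = 8 each), a METTL3 log2 fold change of -0.14 (SE 0.07, edgeR adjusted p = 0.121). METTL3 passed at 30 min alone (-0.45, edgeR adjusted p = 0.0180). Its change over all times passed at -0.18 (edgeR adjusted p = 0.00332) without knockdown-labelled 10 min replicate 1, at -0.17 (edgeR adjusted p = 0.00946) without the 10 min libraries, and at -0.24 (edgeR adjusted p = 0.00158) with the 30 and 60 min libraries only. The METTL3 counts therefore did not check the knockdown labels, whose method the labels do not give, and the groups are named by label from here on.

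The series set out to examine transcription rate, and human gene counts per ERCC count were taken as the amount of captured RNA, which assumes equal spike-in and RNA input in all libraries. Captured RNA per ERCC count was lower in knockdown-labelled libraries at 10 min (1.70 ± 0.00204 against 3.11 ± 0.415 in control), 20 min (6.22 ± 0.216 against 7.10 ± 0.208) and 30 min (12.8 ± 2.06 against 23.8 ± 0.714, SD, n = 2 each). At 60 min it was higher, at 68.7 ± 1.84 against 11.5 ± 0.430, a ratio of 5.96. Control libraries held less captured RNA per ERCC count at 60 min than at 30 min. Averaged over EU times the log2 difference was 0.15 (exact two-sided permutation p = 0.636 over 1296 assignments). The 60 min log2 difference of 2.58 exceeded the mean of the other times by 3.23 (exact permutation p = 0.00154, the smallest those assignments can give). The slope on EU time was 1.40 per min in knockdown-labelled libraries and 0.152 in control, a difference of 1.25 (exact permutation p = 0.00926). Per gene, the median log2 ratio of slopes was 3.30 over 11120 genes with a positive slope in both conditions (permutation p = 0.02, 100 draws). Without the 10 min libraries it was 5.30 over the 4586 genes that then had 2 positive slopes (permutation p = 0.01), with 0.49 for captured RNA (exact permutation p = 0.333) and 1.64 for the slope difference (exact permutation p = 0.00926).

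Without the 60 min libraries these values turned direction, to -0.65 for captured RNA (exact permutation p = 0.00926), -0.477 for the slope (exact permutation p = 0.333) and -0.90 per gene (permutation p = 0.31). The slope call also ended with a slope through the origin (0.614, exact permutation p = 0.333; 1.58 per gene, permutation p = 0.3) and without any 1 of the 4 libraries of the 60 min groups. Those slopes were 1.17 and 1.16 without control replicate 1 or 2, and 1.14 and 1.20 without knockdown-labelled replicate 1 or 2 (exact permutation p = 0.148 each). The call per gene ended at 2.65 and 2.57 without control 60 min replicate 1 or 2 (permutation p = 0.23) and at 3.37 without either knockdown-labelled 10 min replicate (permutation p = 0.13).

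**Figure D1:**
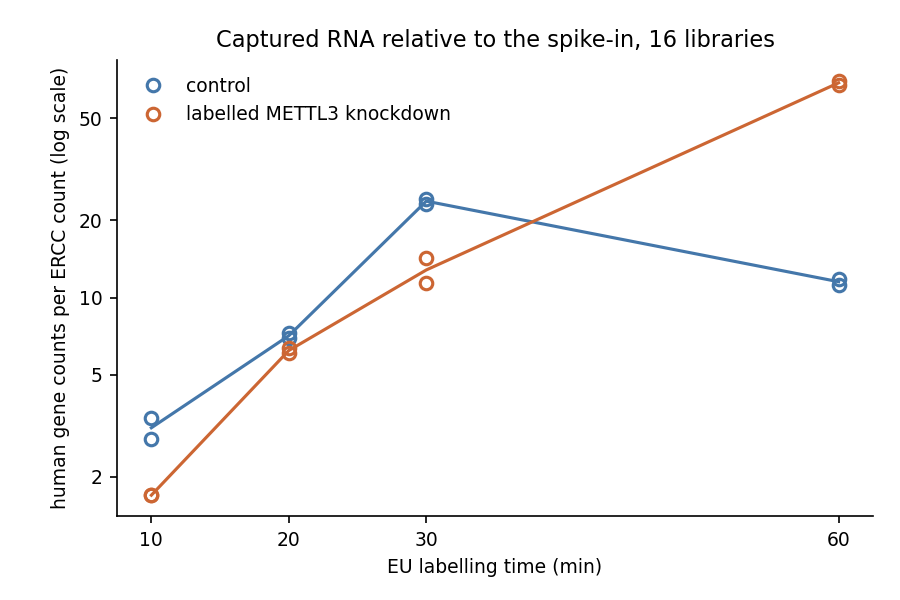
Human gene counts per ERCC count (log scale) against EU time in minutes, with 1 point per library and the group mean, for control and knockdown-labelled libraries. Knockdown-labelled libraries lie below control at 10, 20 and 30 min and above it at 60 min, at a mean of 68.7 against 11.5.

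Scaled to the human transcriptome, MUC5B (ENSG00000117983.17, chromosome 11, 1223066 to 1262172), a secreted gel-forming mucin, rose from 0.880 ± 0.509 to 14.8 ± 6.06 CPM in knockdown-labelled libraries (SD, n = 8 each; log2 fold change 4.01, SE 0.29, edgeR adjusted p = 3.3e-09). GRHL3, a transcription factor of epithelial differentiation, rose by 3.05 (SE 0.23), TRIM29 by 2.68 and KRT13, a keratin of stratified epithelia, by 2.67. SEMA6B, a transmembrane semaphorin (ENSG00000167680.15, chromosome 19, 4542593 to 4559808), rose from 2.47 ± 0.637 to 20.5 ± 5.79 CPM, and PCDH1, a protocadherin, from 7.35 ± 2.02 to 42.2 ± 4.71 CPM. F2R, the thrombin receptor (2.61), NEBL, an actin-binding protein of the nebulin family (2.60), complement factor C5 (2.51), STING1, the adaptor of cytosolic DNA sensing (2.48), PLEKHG1 (2.43) and the long non-coding RNA GRASLND (2.83) completed the 12 largest rises.

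SCEL, which encodes sciellin of the cornified envelope (ENSG00000136155.16, chromosome 13, 77535674 to 77645263), fell from 185 ± 24.6 to 20.7 ± 4.35 CPM (SD, n = 8 each; log2 fold change -3.16, SE 0.08, edgeR adjusted p = 6.4e-15). CD24, a surface glycoprotein (ENSG00000272398.5, chromosome 6, 106969831 to 106975627), fell from 53.1 ± 5.13 to 2.43 ± 1.72 CPM, though CD24 has similar copies elsewhere in the genome, so its counts are less certain. CA12, a membrane carbonic anhydrase (ENSG00000074410.13, chromosome 15, 63321378 to 63382161), fell from 67.2 ± 8.01 to 6.10 ± 1.48 CPM. The kinase gene STK32A (ENSG00000169302.15, chromosome 5, 147234963 to 147387852) had 1425 counts in control and 16 in knockdown-labelled libraries, where 2 groups were at 0, and its mean was 24.8 ± 2.67 against 0.341 ± 0.750 CPM. CXCR4, a chemokine receptor (-3.12), TRPS1, a GATA-type repressor (-3.94), SLCO2B1, an organic anion transporter (-3.81), SCIN, an actin-severing protein (-2.81), TRABD2B (-3.09), SGCE (-2.85), SIRPB1 (-2.77) and LINC01320 (-3.02) were the other large falls. In knockdown-labelled libraries TRPS1 had 50 counts with 2 libraries at 0, SLCO2B1 93 with 1 at 0 and SIRPB1 101 with 1 at 0. Their mean CPM there was 0.102, 0.112 and 0.163 times that of control, so these fold changes rest on few counts.

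In all, 5447 of 19072 genes changed over the 4 EU times, 2457 higher and 2990 lower (edgeR, 7357 at unadjusted p under 0.05), and METTL3 did not check the labels of this comparison. Of these, 3661 had 1 direction at all 4 EU times, which is 67.2% against 13.3% of the genes not called. Genes were called on the mean of these same 4 differences, which by itself raises the share, so it is no separate evidence for the calls. The count rose to 8224 and 8251 without knockdown-labelled 10 min replicate 1 or 2, and fell to 3408 with an additive model. With the 2 libraries of each group summed, which also needs an additive model, it was 879, to be read against 3408. Which direction held more calls depended on the setting: 4156 were higher and 3220 lower without the 10 min libraries, 4035 and 3760 with the 30 and 60 min libraries only, 2374 and 2305 at a mean of at least 5 CPM, 1712 and 1696 in the additive model and 476 and 403 when summed. Of the 116 changed genes named by the fixed rule for this comparison, list members included, 59 passed when summed and 57 did not.

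**Figure D2:**
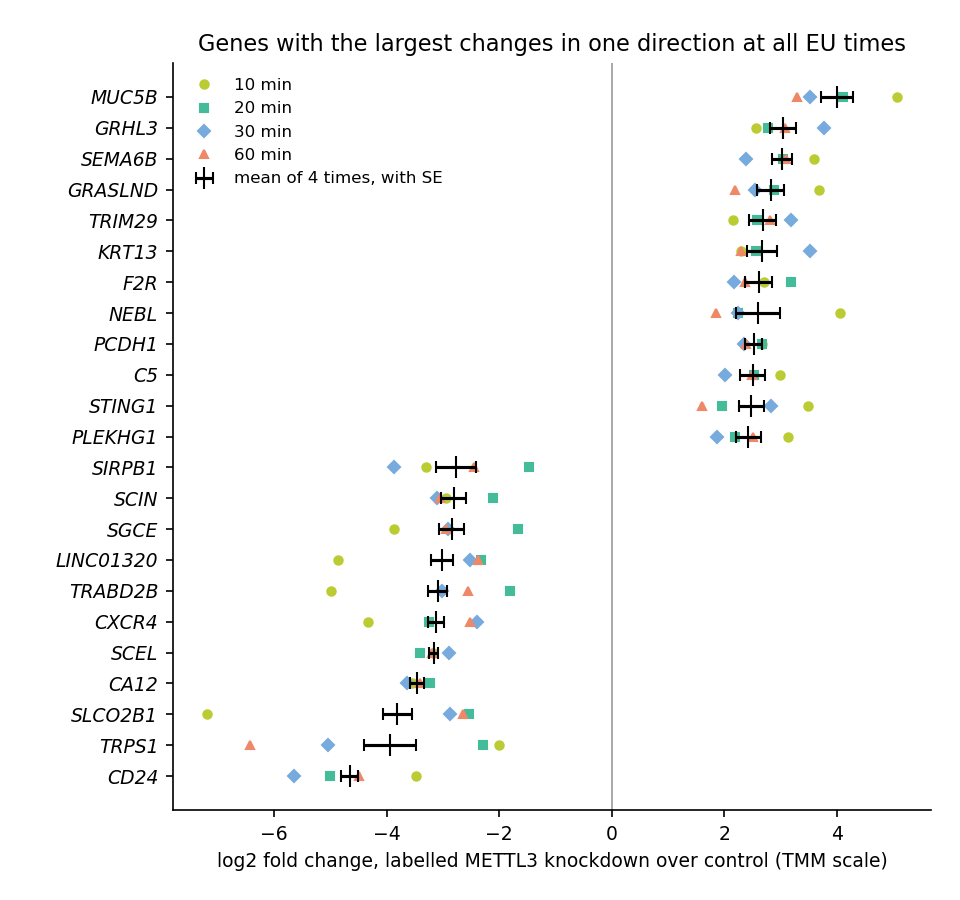
Log2 fold change, knockdown-labelled against control and scaled to the transcriptome, of the named genes with the largest rises and falls. Each EU time and the mean over the times with its SE are drawn, and genes with no counts in a whole group are left out. In CPM, which the figure does not draw, MUC5B has a mean of 0.880 in control and 14.8 in knockdown-labelled libraries, and CD24 53.1 against 2.43.

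Gene lists fixed in advance moved in both directions. Of 34 interferon-stimulated genes, 21 rose, 0 fell and 13 did not pass, with a median log2 fold change of 0.84 (0.77 with genes at a floor of 3 counts over the group). Among them were SAMD9 (1.65), IFIT5 (1.39), DTX3L (0.66) and OAS3 (0.60), and the count was 21 and 0 adjusted over the list alone. Of 34 G2/M and mitosis genes, 25 rose and 1 fell (26 and 1 adjusted over the list alone; median 0.31), such as KIF20A (0.65), CCNB1 (0.54) and TOP2A (0.45). In the TGF-beta and epithelial-mesenchymal list, 14 of 27 rose and 2 fell (15 and 2 adjusted over the list alone), with TGFBR1 (0.70) and LTBP2 (0.58) higher and ITGB1 (-0.40) lower. Among AKT and mTORC2 regulators, 10 of 23 rose and 3 fell (10 and 4 adjusted over the list alone). IRS1 (1.00), IRS2 (0.55) and TSC1 (0.43), an inhibitor of mTORC1, were higher. Limma's camera test gave adjusted p = 8.2e-10 for interferon-stimulated genes, 1.4e-09 for G2/M, 0.00443 for the TGF-beta list and 0.0252 for AKT regulators (adjusted p = 0.0597 with an estimated correlation), all up.

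Of 27 hypoxia and glycolysis genes, 12 fell and 1 rose (12 and 2 adjusted over the list alone), including the angiogenic factor VEGFA (-1.31), NDRG1 (-2.01), PFKFB3 (-0.82) and BNIP3 (-0.73). In the NF-kB list, 9 of 17 fell and 3 rose (the same numbers adjusted over the list alone), with NFKBIZ at -1.54 and NFKB2 at -0.82. The integrated stress and unfolded protein response list had 14 of 30 lower and 3 higher (the same numbers adjusted over the list alone), among them VLDLR (-2.34), the cystine transporter gene SLC7A11 (-0.87) and SLC7A5 (-0.50). Of 21 snoRNA host genes, 13 fell and 0 rose (the same numbers adjusted over the list alone), such as NOP56 (-0.50), SNHG17 (-0.44) and GAS5 (-0.43). Of 3 measured RNA polymerase III and snRNA transcripts, 2 fell (3 adjusted over the list alone), 1 of them RN7SL2 (-0.61), which has near-identical copies and is uncertain. The other measured members were the snRNAs RNU4ATAC and RNU4-2, and "polymerase III list" is only a short name for this list. Camera gave adjusted p = 0.00246 for hypoxia, 0.0115 for NF-kB, 0.0115 for the stress list, 4.2e-05 for snoRNA hosts and 0.0417 for the polymerase III list (adjusted p = 0.242 with an estimated correlation), all down.

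With an estimated correlation, 7 of these 9 calls held, and those of the AKT and polymerase III lists were lost. Using the 30 and 60 min libraries only, camera's adjusted p was 0.101 for hypoxia, 0.101 for the stress list, 0.0676 for snoRNA hosts and 0.416 for the polymerase III list. Summing the 2 libraries of a group gave 0.0623 for the stress, AKT and polymerase III lists. Without knockdown-labelled 10 min replicate 2 the AKT list was at 0.106, and without replicate 1 of that group the polymerase III list was at 0.0879.

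**Figure D3:**
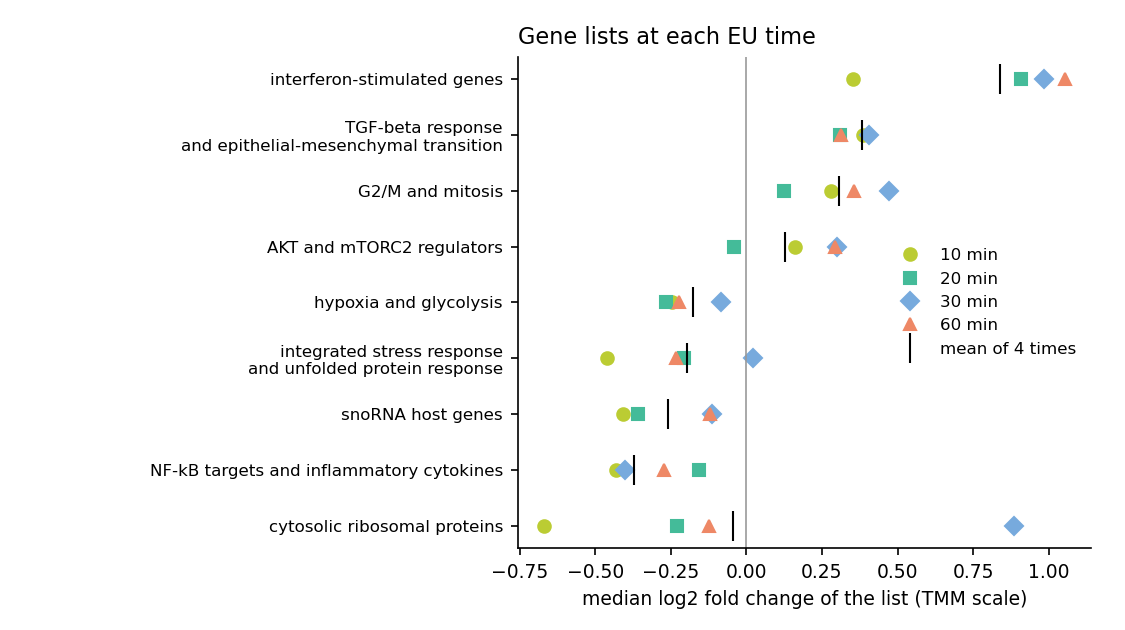
Median log2 fold change, knockdown-labelled against control, of selected gene lists at 10, 20, 30 and 60 min EU, scaled to the transcriptome. Interferon-stimulated genes lie above 0 at each time (0.35 to 1.05), while ribosomal proteins lie at -0.67 at 10 min and 0.89 at 30 min.

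The other 16 lists did not pass camera over the 4 EU times. In the m6A writer complex, 2 of 13 fell and 0 rose (adjusted p = 0.624), with ZC3H13 at -0.35. Among readers and erasers, 4 of 15 rose and 2 fell (0.466), with IGF2BP1 at 1.25 and IGF2BP2 at -0.31. Nuclear RNA surveillance had 1 of 22 higher and 5 lower (0.697), with NCBP1 at 0.45 and SRRT at -0.34. Chromatin regulators had 7 of 34 higher and 12 lower (0.466), including the SWI/SNF ATPase SMARCA4 (-0.45). Polycomb and heterochromatin had 6 of 29 higher and 5 lower (0.858), with DNMT3B at -0.66, DNMT1 at -0.47 and JARID2 at -0.50. The median of this list was 0.01 and its mean -0.03. Immediate-early genes had 8 of 37 higher and 13 lower (0.583), with DUSP4 at 2.30, FOSL2 at -0.99 and JUN at -0.66. Their median was -0.05 and their mean 0.02. The p53 targets had 2 of 23 higher and 4 lower (0.805), with GDF15 at -1.76. GDF15 had 520 counts in control and 328 in knockdown-labelled libraries, 1 of them at 0, and its mean CPM there was 0.574 times that of control. Heat shock genes had 4 of 18 higher and 1 lower (0.624), with HSPB1 at 1.73.

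Cholesterol biosynthesis had 7 of 25 genes higher and 7 lower (adjusted p = 0.858), with INSIG1 at 0.53 and ACAT2 at -0.84, and its median of 0.05 and mean of -0.03 differed in sign. Epithelial and endometrial identity had 7 of 24 higher and 6 lower (0.724). In this list SOX17 (-2.45) and PAX8 (-0.74), transcription factors of the female reproductive tract, were lower, and HOXA10 had 375 counts in control against 48 in knockdown-labelled libraries, with 1 group at 0. S phase and E2F targets had 11 of 35 higher and 6 lower (0.541), with CCNE2 at 0.84 and CHAF1A at -0.46. Replication-dependent histones had 2 of 25 higher and 0 lower (0.358), with a median of 0.17 (0.27 at the floor). Ribosomal proteins had 8 of 76 higher and 18 lower (0.466), mitochondrially encoded genes 6 of 15 higher and 2 lower (0.452), and nuclear-retained long non-coding RNAs 2 of 16 higher and 2 lower (0.746). The last list had a median of -0.01, a mean of 0.11 and a camera direction of up. Markers of fibroblast, immune and endothelial cells had 2 of 7 higher and 0 lower (0.18), with COL1A1 at 3.23 against 7.32 CPM. Their median was 0.02, or 1.04 at the floor, and 2.28 at 20 min, where the knockdown-labelled libraries also detected the most genes.

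Adjusted over the list alone, the higher and lower counts were 7 and 6 for Polycomb, 11 and 13 for immediate-early genes, 9 and 8 for epithelial identity, 12 and 6 for S phase, 8 and 19 for ribosomal proteins and 7 and 2 for mitochondrial genes. The other 10 of these lists had the same counts adjusted over the list alone. With the 30 and 60 min libraries only, 3 lists passed upward in camera: ribosomal proteins (adjusted p = 3.7e-15, opposite in direction to the 4-time result), histones (8.7e-06) and heat shock genes (0.00339).

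Scaled to ERCC counts, the largest changes stayed large. MUC5B was at a log2 fold change of 4.17, CD24 at -4.49, CA12 at -3.28 and SCEL at -2.99. The median over all genes was 0.161 on this scale and -0.017 on the transcriptome scale. In all 5399 genes passed, 4217 higher and 1182 lower (edgeR, 7387 at unadjusted p under 0.05), so that 78.1% of the called genes were higher against 45.1% on the transcriptome scale. List medians moved up with this shift of all genes, and that of the hypoxia list, -0.18 (-0.11 at the floor) on the transcriptome scale, lay at 0.07. METTL3 was at 0.03 (edgeR adjusted p = 0.838) and did not check the labels here either. Without the 60 min libraries 11287 genes passed, 316 higher and 10971 lower, and METTL3 turned to -0.83 (edgeR adjusted p = 1.5e-07). METTL3 was higher in knockdown-labelled libraries on this scale without the 10 min libraries (0.32, edgeR adjusted p = 0.000338) and with the 30 and 60 min libraries only (0.61, edgeR adjusted p = 1.5e-07). The count was 12412 without the 10 min libraries, 13713 with the 30 and 60 min libraries only, 117 with an additive model and 1 with the libraries of each group summed, also in an additive model.

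At single EU times, interferon-stimulated genes had medians of 0.35, 0.91, 0.98 and 1.05 at 10, 20, 30 and 60 min. Camera's adjusted p was 0.00208 at 10 min (adjusted p = 0.0956 with an estimated correlation), 1.3e-08 at 20 min, 1.1e-05 at 30 min and 1.3e-10 at 60 min, and the 60 min median was 0.94 at the floor. At 20 min, where the knockdown-labelled libraries stood apart in genes detected, the markers of other cell types passed upward too (camera adjusted p = 0.0021, 0.0417 with an estimated correlation), with 0 of 7 genes called. MUC5B was at 5.07, 4.12, 3.53 and 3.30 and VEGFA at -1.84, -1.26, -1.07 and -1.06. Ribosomal protein genes fell at 10 min, where 65 of 76 were lower and 0 higher (66 and 0 adjusted over the list alone; median -0.67, camera adjusted p = 5.6e-19). At 30 min 71 of 76 rose and 0 fell, also adjusted over the list alone (median 0.89, camera adjusted p = 1.6e-41). A further list of 36 abundant stable mRNAs outside the ribosomal proteins had medians of -0.45 at 10 min and 0.56 at 30 min. These shifts were therefore not particular to ribosomal protein genes. At 10 min 13 of 15 mitochondrially encoded genes rose and 1 fell, also adjusted over the list alone (median 0.81, camera adjusted p = 1.1e-08, or adjusted p = 0.0956 with an estimated correlation), such as MT-ND3 (1.16). The median of this list lay the other way at 20 min (-0.15), 30 min (-0.14) and 60 min (-0.21). The libraries labelled knockdown at 10 min stood apart in the 10 min comparison, with 18201 and 18576 genes detected and a spread between replicates of 19.0 times counting error, against 2.17 to 4.74 in the other groups.

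The called genes numbered 5473 at 10 min (2227 higher, 3246 lower), 919 at 20 min (382 and 537), 3859 at 30 min (2132 and 1727) and 1109 at 60 min (486 and 623; edgeR). METTL3 passed at 30 min alone, where the knockdown-labelled libraries also stood apart in ribosomal protein genes, so this is a weak check of the labels. It did not check the labels at the other 3 times. Of 919 genes called at both 30 and 60 min, 883 had the same direction, as did 488 of 498 called at both 20 and 60 min and 1154 of 1834 called at both 10 and 30 min. With upper-quartile scaling the 20 min calls were 462 higher and 369 lower, and the 30 min calls 1713 higher and 2088 lower, so the majority direction at both times depended on the scaling. It depended on the filter at each time: at a mean of at least 5 CPM the higher and lower calls were 2222 and 2055 at 10 min, 440 and 430 at 20 min, 2018 and 2054 at 30 min and 616 and 615 at 60 min, and with no filter 641 and 560 at 60 min. Single libraries moved these counts, in parentheses with replicate 1 and then 2 left out. At 10 min they were the control 10 min replicate 1 (3643) and knockdown-labelled 10 min libraries (8235, 8552). At 20 min they were the control 20 min (362, 422), knockdown-labelled 20 min (453, 434) and knockdown-labelled 10 min libraries (2771, 2775). At 30 min they were the control 30 min (2179, 2141), knockdown-labelled 30 min (2292, 2182) and knockdown-labelled 10 min libraries (6316, 6321). At 60 min they were the control 60 min replicate 1 (475), knockdown-labelled 60 min (435, 556) and knockdown-labelled 10 min libraries (2827, 2825).

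The knockdown-label effect depended on EU time for 3054 genes (edgeR F test of the interaction, 5776 at unadjusted p under 0.05), and the 6 with the lowest p were led by ribosomal protein genes. RPL35 (ENSG00000136942.14, chromosome 9, 124857880 to 124861981) had log2 fold changes of -0.81, 0.24, 1.88 and 0.18 at 10, 20, 30 and 60 min (edgeR adjusted p = 1.6e-12). S100A6, a calcium-binding protein, was at -1.09, -0.10, 1.58 and -0.19, and RPL27 was at 1.41 at 30 min. RPL18, RPL19 and RPL23 were at 1.29, 1.09 and 1.14 at 30 min and at -0.93, -1.18 and -0.72 at 10 min. As a list, ribosomal proteins at 30 min differed from the mean of the other times by a median of 1.24 (camera adjusted p = 7.6e-65, 0.00105 with an estimated correlation). Ribosomal protein genes took 4.15% of human counts in the knockdown-labelled 30 min libraries (41488 ± 876 CPM, n = 2) and 2.26% in control at 30 min. Across the other 6 groups they took 1.65% to 2.69%. The interaction count was 1867 with 1 contrast linear in log2 EU time, 2022 without control 30 min replicate 2, 1990 without knockdown-labelled 30 min replicate 2, and 7927 and 7992 without knockdown-labelled 10 min replicate 1 or 2.

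**Figure D4:**
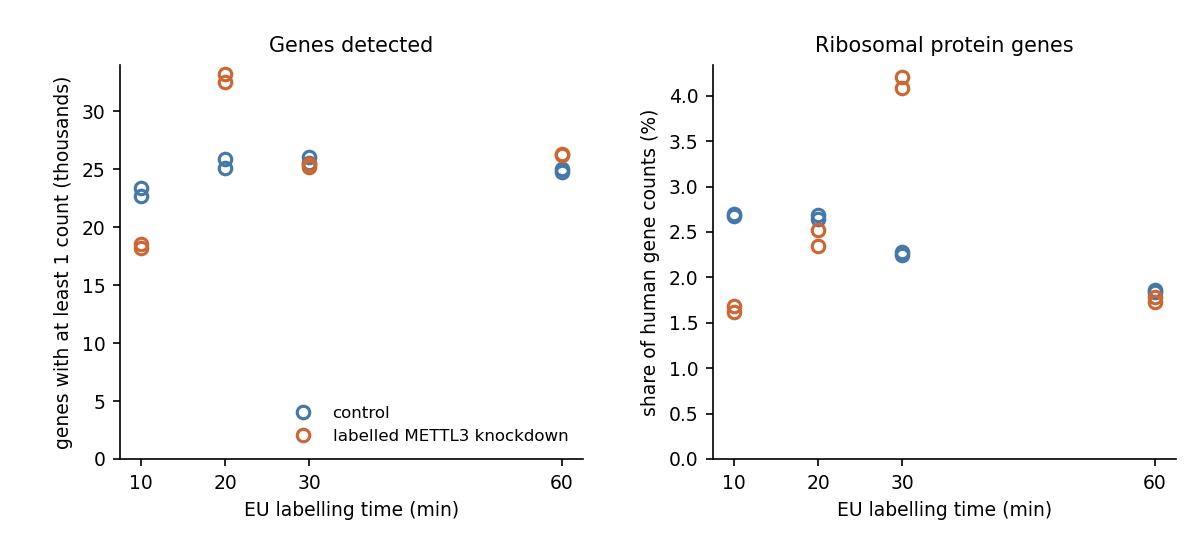
Genes detected and the ribosomal protein share of human gene counts (%) in each of the 16 libraries, against EU time in minutes. The knockdown-labelled 10 min libraries detected 18201 and 18576 genes, and the knockdown-labelled 30 min libraries held 4.15% of counts on ribosomal protein genes on average.

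In control libraries, TIPARP, a target of the aryl hydrocarbon receptor (ENSG00000163659.12, chromosome 3, 156673235 to 156706770), rose by 1.26 log2 per doubling of EU time (SE 0.08, edgeR adjusted p = 1.9e-09), from 36.4 CPM at 20 min to 247 CPM at 60 min (n = 2 each). CYP1A1, a cytochrome P450 induced through the same receptor (ENSG00000140465.13, chromosome 15, 74719542 to 74725610), rose by 1.17 (SE 0.11). SOX17 rose by 1.01, the vasodilator peptide gene ADM by 0.95, ZBTB14 by 0.94, DDIT4, an inhibitor of mTORC1, by 0.90 and THBD, thrombomodulin, by 0.87. The small nucleolar RNAs SNORD3C (-1.02) and SNORD12C (-0.68), the mitochondrial proline tRNA MT-TP (-0.66) and the histone gene H4C15 (-0.65) fell. SEPTIN14P12 (-0.84) is a pseudogene with related copies, so its value is uncertain. In all 2405 genes changed with EU time, 1395 higher and 1010 lower (edgeR, 4538 at unadjusted p under 0.05). The count was 5088 without the 10 min libraries, 4205 fitted to control libraries alone, and 1487 and 1602 without control 10 min replicate 1 or 2. It was 1432 and 1468 without control 60 min replicate 1 or 2, and 4661 and 4645 without knockdown-labelled 10 min replicate 1 or 2, which enter this contrast through the shared spread alone.

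Of 37 immediate-early genes, 30 rose with EU time in control libraries and 0 fell (32 and 0 adjusted over the list alone; median slope 0.49, camera adjusted p = 2.1e-32). MYC (ENSG00000136997.17, chromosome 8, 127735434 to 127741434) rose from 198 ± 7.39 CPM at 10 min to 708 ± 25 at 60 min (SD, n = 2 each), a slope of 0.71, and JUN (0.66), KLF6 (0.58) and CCN1 (0.45) rose too. Of 76 ribosomal protein genes, 64 fell and 0 rose (69 and 0 adjusted over the list alone; camera adjusted p = 2.1e-32), such as RPS15A (-0.41), RPL32 (-0.37) and RPS14 (-0.34). The 36 abundant stable mRNAs outside the ribosomal proteins moved in control by a median log2 of -0.35 from 10 to 30 min. From 30 to 60 min their median was -0.05. In the NF-kB list 7 of 17 rose and 0 fell (8 and 0 adjusted over the list alone), among them the feedback inhibitors TNFAIP3 (0.63) and NFKBIA (0.59). The stress list had 9 of 30 higher and 0 lower (12 and 1 adjusted over the list alone), with DNAJB9 at 0.67 and SLC7A5 at 0.37. The TGF-beta list had 8 of 27 higher and 1 lower (11 and 1 adjusted over the list alone), with SMAD7 (0.59) and ID1 (0.45), both direct targets of this signalling family. Camera's adjusted p was 0.000448 for NF-kB, 0.00225 for the stress list and 0.00183 for TGF-beta, and these 5 calls held with an estimated correlation.

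In the mitochondrial list 12 of 15 genes rose and 1 fell (12 and 2 adjusted over the list alone), such as MT-CO1 (0.33) and MT-CO3 (0.32), with camera adjusted p = 3.9e-06 and adjusted p = 0.193 with an estimated correlation. Of 23 p53 targets 6 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0151; adjusted p = 0.0559 with an estimated correlation). AEN rose by 0.35 and CDKN1A, a cyclin-dependent kinase inhibitor, by 1.15, though CDKN1A was at 0.86 (edgeR adjusted p = 0.0650) without control 10 min replicate 1 and at 0.51 (edgeR adjusted p = 0.0792) without the 10 min libraries. Of 3 polymerase III and snRNA transcripts 1 fell (2 adjusted over the list alone; camera adjusted p = 0.0266, adjusted p = 0.193 with an estimated correlation). That transcript was RN7SL2 (-0.41), which was at -0.35 (edgeR adjusted p = 0.103) without control 60 min replicate 2. The other 17 lists had adjusted p of 0.129 to 0.973, the lowest for heat shock genes and AKT regulators. The AKT list passed at 0.0362 without control 60 min replicate 1.

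In knockdown-labelled libraries EU time changed 6263 genes, 3668 higher and 2595 lower (edgeR, 8292 at unadjusted p under 0.05). TIPARP rose by 1.72, CYP1A1 by 2.01, SOX17 by 1.13 and MYC by 0.84. TIPARP, CYP1A1 and SOX17 were named by a rule that required the same direction here as in control, so their direction is no separate evidence. Of 1658 genes called in both conditions, 1521 went the same way, 1039 up and 482 down, where 790 shared calls would follow from the sizes alone. Of 37 immediate-early genes 33 rose and 0 fell (36 and 0 adjusted over the list alone; camera adjusted p = 2.4e-15, 0.00135 with an estimated correlation). The 2 trends differed for 1867 genes, 1244 with the greater slope in knockdown-labelled libraries and 623 with the smaller. Ribosomal proteins differed by a median of 0.30 per doubling (camera adjusted p = 1.4e-27, 0.0181 with an estimated correlation). The trend count was 3720 and 3582 without knockdown-labelled 60 min replicate 1 or 2, and 4018 fitted to the knockdown-labelled libraries alone. METTL3 did not check the labels of these groups.

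**Figure D5:**
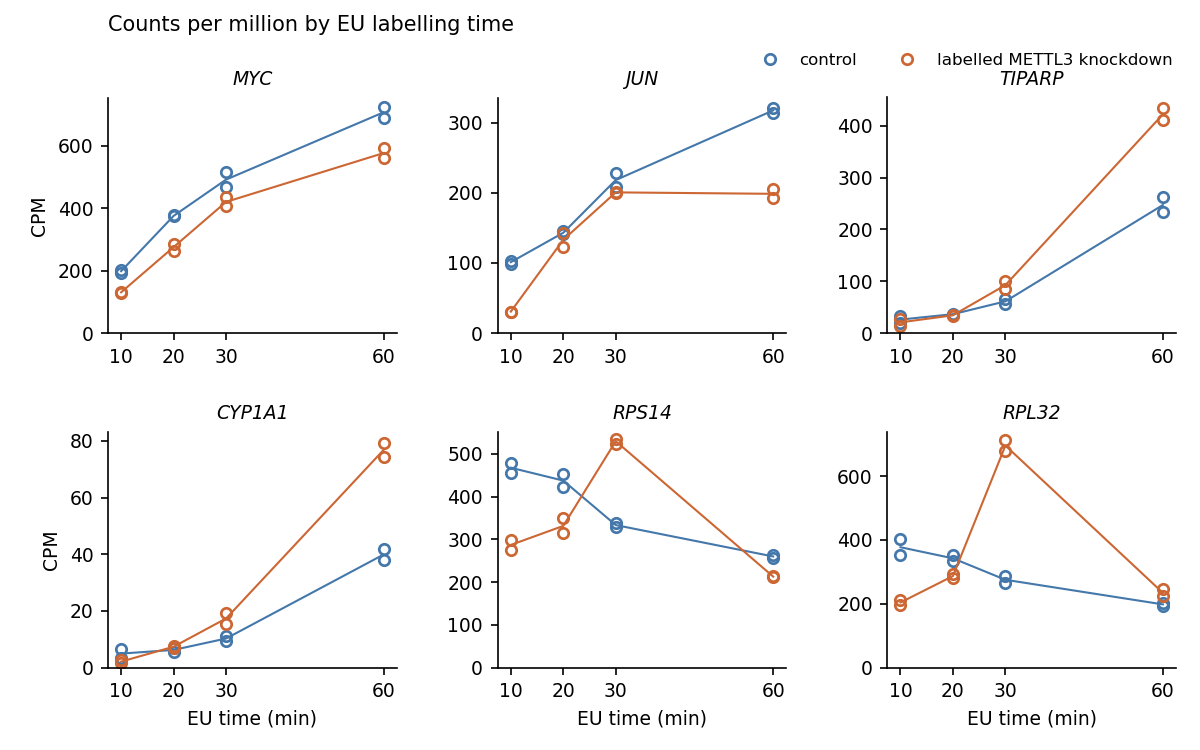
CPM (linear scale) of genes that gained or lost share with EU time in minutes, with 1 point per library and the group mean, in control and knockdown-labelled libraries. MYC rises in control from a mean of 198 CPM at 10 min to 708 at 60 min.

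Small nucleolar RNAs took a smaller share of human counts in knockdown-labelled libraries, 0.0312% ± 0.00817 against 0.0458% ± 0.0135 in control (SD, n = 8 each; exact two-sided permutation p = 0.00154, the smallest of 1296 assignments; 0.0139 adjusted over 9 classes). The class of miscellaneous small RNAs, which holds the 7SL and Y RNA genes and their copies, was at 0.173% ± 0.0821 against 0.252% ± 0.0797 (exact permutation p = 0.0108, adjusted 0.0486). Much of this class was the 7SL gene RN7SL2, with a mean of 1203 CPM in knockdown-labelled libraries and 1805 CPM in control. RN7SL3, another 7SL gene, had a mean CPM 0.266 times that of control. Counts of such multi-copy genes are uncertain, so the difference of this class rests largely on uncertain counts. Spliceosomal small nuclear RNAs were at an adjusted exact p of 0.0833, and the other 6 classes between 0.539 and 0.940. These included protein-coding genes (86.6% in both conditions), mitochondrially encoded genes (7.42% in control and 7.60% in knockdown-labelled libraries) and reads outside annotated exons (57.6% and 55.4%, but 59.2% and 47.9% at 30 min). Mitochondrial genes took 9.86% ± 0.545 in the knockdown-labelled 10 min libraries and 6.14% ± 0.144 in control at 10 min (n = 2 each). At the other times their share was lower in knockdown-labelled libraries, at 6.49% against 7.28% at 20 min, 6.42% against 7.60% at 30 min and 7.63% against 8.67% at 60 min.

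Small nucleolar RNAs were at 0.0262% in knockdown-labelled libraries against 0.0446% in control at 30 min, and at 0.0224% against 0.0263% at 60 min. The count of classes past the threshold, 2, was 1 without any 1 of 9 libraries: control 10 min replicate 1, 20 min replicate 2, 30 min replicate 1 and 60 min replicate 1, and knockdown-labelled 10, 20 and 60 min replicate 1 and both 30 min replicates. The adjusted exact permutation p of miscellaneous small RNAs was then between 0.0556 and 0.118.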

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

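Of the tests in this part, all those on captured RNA, the one on silent genes opened by METTL3 knockdown, those on longer labelling and on higher ribosomal protein transcription, and the splits for the gene counts were chosen after the result was seen.

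Captured RNA per ERCC count differed between EU times in its knockdown-label effect, with a 60 min log2 difference 3.23 above the mean of the other times. An exchange of the control 30 and 60 min groups is argued against by 2783 genes that rose with EU time in knockdown-labelled libraries: in control they were higher by a median log2 of 0.277 at 60 min than at 30 min, with an SD between libraries of 0.0086. Spike-in volume or RNA input differing between plates stays a candidate explanation, since control libraries held 0.485 times as much captured RNA per ERCC count at 60 min as at 30 min, a fall that longer labelling alone would not give. More RNA made per minute in knockdown-labelled cells would raise the ratio at each EU time and it was higher at 1 of 4, but the ratio rests on the same spike-in, so this cannot be told apart. The dependence on EU time passed its test (exact permutation p = 0.00154), but a biological difference as its source stays open, because each group may come from 1 plate.

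The knockdown-labelled 20 min libraries held counts in a gene family on which no comparison was planned, with 105 ± 1.39 CPM on 381 olfactory receptor genes against 24.7 ± 4.22 in control at 20 min (SD, n = 2 each). Library depth is argued against, since with every library thinned to 5187965 counts the lower of these 2 libraries still detected 1.29 times as many genes as the highest other library. Silent genes that METTL3 knockdown opened at all EU times are argued against, since the knockdown-label to control ratio of olfactory receptor CPM was 0.586 at 30 min and 1.16 at 60 min, though at 10 min the values were 32.1 against 21.4 CPM. Background from genomic DNA could raise every silent family, and 3 of 5 families, olfactory receptors, beta-defensins and, by a small margin (0.0330 against 0.0326 per kb of exon), keratin-associated proteins, were higher in both libraries than in every other. Bitter taste receptors were higher in control libraries. At 0.135 to 0.520 per kb of exon across the libraries they were not silent here, so they could not show a low background. Late cornified envelope genes were highest in 1 knockdown-labelled 10 min library, so the families do not all agree. Reads outside annotated exons were 64.9% in the knockdown-labelled 20 min libraries and 62.1% in control at 20 min. Genomic DNA cannot be told apart from other sources of background.

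Ribosomal protein genes had a knockdown-label effect at 30 min that differed from the mean of the other EU times by a median log2 of 1.24. Labelling for longer than stated is argued against as the whole cause, since ribosomal protein CPM at 30 min in knockdown-labelled libraries exceeded the mean of all 60 min libraries by 1.20 on the log2 scale. It stays open beside another cause, since these libraries were near the 60 min groups in reads outside exons (47.9% against 49.2% in control and 46.8% in knockdown-labelled libraries at 60 min, and 59.2% in control at 30 min). Carry-over of unlabelled mature RNA may account for the pattern: 36 other abundant stable mRNAs had a median log2 fold change of 0.56 at 30 min, and 31 of them were higher and 1 lower. Higher ribosomal protein transcription in these cells cannot be told apart from this, because the medians of -0.23 at 20 min and -0.13 at 60 min restate the pattern and a change at 30 min alone was not tested.

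The interaction between knockdown label and EU time passed for 3054 genes, which is a difference between EU times in itself. The EU time trends of replication-dependent histones also differed between conditions, by a median of 0.52 log2 per doubling of EU time.

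Other splits of the 16 libraries within EU time were compared, 100 drawn with the real one among them. They gave at most 3592 genes on the transcriptome scale against the real 5447, so 1 of 100 was as large. For the gene lists 3 of 100 splits gave as many as the real 9, with a highest other of 11 and a median of 2. Such splits can put libraries of both labels in 1 group, which widens the spread within it, and their median was 0 genes. Groups that differ for any reason would stand out in this way, so neither share excludes chance. On the ERCC scale 17 of 100 splits gave as many as the real 5399, with a highest other of 15736, so chance cannot be excluded. A split with several times the real count points to a structure of the samples. If the 2 libraries of a group share a plate, there are 8 arrangements of whole groups, too few for a share under 0.05. The other 7 gave 576 to 3592 genes on the transcriptome scale, 5458 to 16387 on the ERCC scale and 3 to 10 lists, with 10 when the 30 min groups were exchanged.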

How the results depend on the processing

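Of the alternatives below, leaving out the 10 min libraries for the trend, leaving out the 60 min libraries for captured RNA, using the 30 and 60 min libraries only, summing groups, adding reads outside exons to captured RNA and exchanging whole groups were chosen after the data were seen. Of 351 comparison values under alternatives, 278 kept their direction and side of the threshold, or a count within 1.5 times, 49 were weaker, 21 stronger and 3 reversed. For single genes and lists the numbers were 8101, 246, 50 and 15, and 83 of the weaker values came from summing the 2 libraries of each group, which leaves 8 libraries. RLE factors (5473 genes), upper-quartile scaling (5462), no filter (5446), a mean of at least 5 CPM (4679) and DESeq2 (5643) kept the transcriptome-scale count near 5447. A replicate block gave 5336; the pairing check found 28 correlations between groups' replicate differences of -0.104 to 0.0729, with a median of -0.00415 and 0 above 0.1, which gives no sign of pairing by replicate number.

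Without the 60 min libraries, captured RNA (-0.65), its slope (-0.477), the slope per gene (-0.90) and METTL3 on the ERCC scale (-0.83) reversed, and 11287 genes passed on the ERCC scale. METTL3 was at 0.32 on that scale without the 10 min libraries and at 0.61 with the 30 and 60 min libraries only, past the threshold in both. Adding reads outside exons gave 0.0861 for captured RNA and 2.66 for its slope. A slope through the origin gave 0.614 and 1.58 per gene. Exchanging whole groups left the slope difference at 1.25 and 0 annotation classes past the threshold, but 16 assignments are too few for either to pass, so this says nothing on stability. With the 30 and 60 min libraries only, 13713 genes passed on the ERCC scale, and 0 classes, though 36 assignments are too few for any to pass. CBX5 (-0.0081), HSP90AB1 (0.0256), RPL28 (0.0431), RPL6 (0.14), MT-CYB (-0.18) and the ribosomal protein list (14.4, as a signed -log10 of the adjusted p) reversed there. Without the 10 min libraries 12412 genes passed on the ERCC scale and 5088 in the control trend. HSP90AB1 (0.0221), RPL6 (0.0191) and MT-CYB (-0.11) reversed in the knockdown-label effect, and SCNN1D (-0.44), XRN2 (0.17), ATRX (0.0604), HSP90AA1 (0.0081) and HSPA4 (0.10) in the control trend. The additive model gave 3408 genes and 117 on the ERCC scale, and summed groups, which need an additive model too, 879 and 1, to be read against these. One linear contrast gave 1867 interaction genes, and fits to each condition alone gave 4205 in control and 4018 in knockdown-labelled libraries. With fry, which asks another question, 19 lists passed for the knockdown label and 15 for the control trend, and camera with an estimated correlation passed 5 for the trend. Except where fewer libraries or another question account for a change, the cause was not tested.

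Leaving out each library in turn gave 0.113 to 0.196 for captured RNA, 1.14 to 1.32 for its slope, 2.57 to 3.99 per gene, 1 to 3 annotation classes, 4296 to 8251 genes over all EU times and 4223 to 7240 on the ERCC scale. Counts were 3643 to 8552 at 10 min, 362 to 2775 at 20 min, 2141 to 6321 at 30 min, 435 to 2827 at 60 min, 1990 to 7992 for the interaction, 1432 to 4661 for the control trend and 3582 to 9003 for the knockdown-labelled trend. Both set-test counts were 8 to 9. The highest of each of these gene counts came without 1 of the knockdown-labelled 10 min libraries, the group whose replicates differed most (median absolute log2 difference 0.405, against 0.0979 to 0.181 in the other groups). In these fits the lone library of a group is assumed to vary like the other groups. Depth limits the genes at few counts: 10 lists held a gene with a whole group at 0, and 2 list medians changed sign with such genes at the floor.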

Other observations

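The set tests on EU time in knockdown-labelled libraries and at single EU times were chosen after the result was seen, and the tests on immediate-early genes and on copy number before it.

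With longer EU labelling in knockdown-labelled libraries, 11 of 25 replication-dependent histone genes rose and 0 fell, also adjusted over the list alone (median 0.61 log2 per doubling of EU time; camera adjusted p = 0.000435, 0.0203 with an estimated correlation). H4C3 rose by 0.72, H2AC6 by 0.61 and the linker histone H1-2 by 0.39. In control libraries 0 rose and 1 fell, and the trends differed between conditions (camera adjusted p = 0.000118, 0.0181 with an estimated correlation). Of the 25 genes, 6 had a whole group at 0 in knockdown-labelled libraries, where the 10 min libraries detected the fewest genes. In the stress list 16 of 30 rose and 0 fell (17 and 1 adjusted over the list alone; camera adjusted p = 0.000435, 0.0203 with an estimated correlation), among them XBP1 (0.65) and ATF4 (0.36), transcription factors of these responses, and the chaperone HSPA5 (0.30). Heat shock genes had 10 of 18 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0415; adjusted p = 0.235 with an estimated correlation). NF-kB targets had 7 of 17 higher and 1 lower (9 and 2 adjusted over the list alone; 0.0415; adjusted p = 0.139 with an estimated correlation), and the TGF-beta list 10 of 27 higher and 2 lower (11 and 2 adjusted over the list alone; 0.0415; adjusted p = 0.132 with an estimated correlation). Mitochondrially encoded genes had 1 of 15 higher and 11 lower, also adjusted over the list alone (0.000435; adjusted p = 0.306 with an estimated correlation), and ribosomal proteins 41 of 76 higher and 9 lower (42 and 11 adjusted over the list alone; 0.00812; adjusted p = 0.347 with an estimated correlation). The trends of ribosomal proteins (camera adjusted p = 1.4e-27, 0.0181 with an estimated correlation), mitochondrially encoded genes (6.5e-12; 0.107) and heat shock genes (0.000519; 0.106) also differed from control with the preset correlation. Differences did not pass for the stress (0.528), NF-kB (0.988) and TGF-beta (0.945) lists.

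At single EU times, hypoxia and glycolysis genes were lower in knockdown-labelled libraries at 20 min, where 6 of 27 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 9.7e-06, 0.00814 with an estimated correlation). At 60 min the counts were the same (camera adjusted p = 6.9e-06, 0.00688 with an estimated correlation), while at 30 min 6 fell and 5 rose (7 and 5 adjusted over the list alone; median -0.08, camera adjusted p = 0.493). At 10 min 10 fell and 2 rose (13 and 2 adjusted over the list alone; 0.024, or adjusted p = 0.0861 with an estimated correlation). Of 21 snoRNA host genes 12 fell and 0 rose at 20 min (15 and 0 adjusted over the list alone; 5.7e-08, 0.00552 with an estimated correlation). At 10 min 12 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.0084, or adjusted p = 0.0733 with an estimated correlation), at 30 min 7 fell and 3 rose (8 and 3 adjusted over the list alone; adjusted p = 0.147), and at 60 min 3 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0609). Heat shock genes rose at 30 min, 12 of 18 with 0 lower (14 and 0 adjusted over the list alone; 2.6e-05, 0.0434 with an estimated correlation), in the libraries that also held the highest ribosomal protein share. At 10 min 8 of them were lower and 1 higher, also adjusted over the list alone (median -0.31, camera adjusted p = 0.0548), and the 10 min effect differed from the other times (camera adjusted p = 0.00339; adjusted p = 0.104 with an estimated correlation). G2/M genes rose at 60 min, 14 of 34 with 0 lower (20 and 0 adjusted over the list alone; 8.1e-11, 0.00397 with an estimated correlation). They also passed upward at 10 min (16 higher and 1 lower, 19 and 1 adjusted over the list alone; 0.000135, 0.0418 with an estimated correlation), 20 min (4 and 0, 6 and 0 adjusted over the list alone; 0.0346, or adjusted p = 0.115 with an estimated correlation) and 30 min (22 and 3, 25 and 3 adjusted over the list alone; 2.0e-07, 0.00803 with an estimated correlation).

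The rise of immediate-early genes with EU time could be a response to handling or EU addition at different times before collection, as a pulse that has passed its peak by 60 min. The median log2 CPM of the primary immediate-early genes was higher at 60 min than at 30 min by 0.507 in control libraries, which argues against such a pulse there. In knockdown-labelled libraries it was higher by 0.053, but members went both ways. From 30 to 60 min EGR1 went from 7.92 to 7.63 and NR4A1 from 4.54 to 4.25, while FOSB went from 6.10 to 6.83 and IER3 from 1.83 to 2.44. That median therefore does not decide the question for those libraries. A response still rising at 60 min was not tested.

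Copy number differing between the control and knockdown-labelled cells might shift neighbouring genes together. Over 152 windows of 20 Mb with 11842 genes, the SD of window medians of the log2 fold change was 0.108 against a median of 0.0459 when genes were shuffled, 2.36 times as large. The highest SD in 1000 shuffles was 0.0574. The lowest window, the first 20 Mb of chromosome 5, had a median of -0.34 over 42 genes. The highest lay on chromosome 9, with 0.41 over 29 genes. The windows that follow it there had 0.37 (80 genes), 0.36 (58) and 0.28 (200), while the first windows of that chromosome had -0.04 and -0.02. On chromosome 21 the windows were at 0.33 and 0.17. Whether such runs of windows exceed those of shuffled genes was not tested. Neighbouring genes that are regulated together would also raise the SD of window medians, so copy number cannot be told apart from that. A copy number difference would enter the 5447 calls over all EU times, which were not adjusted for it.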
